A study of Homo sapiens with 9 samples.

How the data were processed

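RNA from 9 libraries was measured: 3 of proximal, 3 of distal and 3 of monocultured THP-1 macrophages. Per the labels, THP-1 cells were differentiated with 250 nM PMA for 48 h and cocultured for 24 h with HER2-positive MDA-MB-231 cells, at 20 macrophages per tumour cell in the series design and 40 in the growth protocol. Per the labels, cells were incubated with a HER2-binding affibody fused to beta-galactosidase at 2 µg/mL for 30 min, with the quinone-methide biotin probe for 10 min and with fluorescent streptavidin for 30 min, and were then sorted. Whether monocultured cells were labelled and sorted in the same way is not given in the sources used here. Per the labels, polyadenylated RNA was sequenced as paired reads of 150 bp.

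The values are counts of read pairs per gene name, deposited by the authors without normalization, in 3 tables of 3 libraries each. Per the file headers, pairs were counted with featureCounts 1.6.3 over exons grouped by gene name on GENCODE release 36, with strand not used; pairs mapping to several places or overlapping several genes were left out by that command. Per the labels, reads were trimmed with Trim Galore 0.6.5 and aligned with STAR 2.7.6a to GRCh38.p13, and the authors worked with R 4.1.3 and DESeq2 1.34.0. The tables are headed H, L and M, which were read as high labelling (proximal), low labelling (distal) and monocultured; no label gives this key in words, and the values were not used to choose it. Library totals were 13581994 to 16447199 pairs over 61180 gene names, of which 2304 lie on more than one sequence of the annotation. Such genes, and genes overlapped by the exons of others, lose their pairs, so a count of 0 for them shows nothing.

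Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15; 15427 genes left), TMM factors, and a robust quasi-likelihood fit of all 9 libraries with 1 coefficient per group, which leaves 6 residual degrees of freedom (biological coefficient of variation 11.6%). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called, higher and lower apart, in 3 comparisons: proximal against distal, proximal against monocultured, and distal against monocultured. Standard errors are those of the fitted log2 fold changes. The 28 gene lists were fixed in advance, and lists with at least 5 measured members were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry were run beside it. List members were also adjusted over the list alone. Some genes belong to several lists, so the calls of different lists are not independent. The log2 changes of the 2 gates against their shared controls were compared by Pearson correlation and covariance with 100 simulated sets of unchanged groups. Summed tumour marker CPM were compared by exact permutation, which cannot give a p under 0.1 with 3 against 3. GC content came from the longest transcript of each gene name in a GENCODE transcript set and was known for 96.5% of the genes tested. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

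Named genes were chosen by a rule: in each comparison, the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean of at least 5 CPM in the higher group and no overlap between replicates, clone-type names apart; up to 4 members of each described list with the smallest p; and ERBB2 with the 4 most abundant tumour markers. The groups, tests, lists, this rule and most alternatives were set before the data were examined. These alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, the DESeq2 Wald test, limma voom, no filter, a filter of 50 counts in 3 libraries, a fit of only the 2 groups compared, replicate number as a block, glmTreat against a 1.5-fold change, leaving out mitochondrial and the 20 most abundant genes, and leaving out each library in turn. Chosen after seeing the data were removal of each library's GC trend, a restriction to countable genes (at least 50% of exonic bases free of other genes and no copy on a patch or haplotype sequence), and leaving out proximal replicate 3 with distal replicate 2.

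The procedure was tested on simulated data for proximal against distal, with 200 of 15067 genes changed. It recovered 20 of 67 genes changed 1.5-fold (29.9%), 49 of 67 changed 2-fold (73.1%) and 61 of 66 changed 4-fold (92.4%). A further 30 genes were shifted together as a list. Of 142 calls, 10 were of unchanged genes (7.04%) and 2 were of the 30 shifted genes. Among the changed genes 0 were called in the wrong direction. Camera called 0 of 50 random lists. The simulated genes were drawn independently, whereas members of real lists can be correlated (estimated at 0.327 for immediate early and dissociation genes). The random lists thus do not show how often camera calls correlated lists at the preset correlation. No library and no count column was left out of the tests; strand and isoforms were not analysed here, since the counts are per gene name.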

Results

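THP-1 cells, a human monocytic leukaemia line, were turned into macrophages with 250 nM PMA over 48 h and then cultured for 24 h with HER2-positive MDA-MB-231 cells, a human breast cancer line that here carries the receptor ERBB2. An enzyme bound to HER2 on the tumour cells was used to release a reactive biotin probe near them. The biotin on a macrophage was taken to measure its closeness to a tumour cell at the time of labelling, which was not tested here. Cells were sorted by that signal into a proximal gate (high labelling) and a distal gate (low labelling), and macrophages never cultured with tumour cells were the control. Polyadenylated RNA was sequenced from 3 libraries in each of the 3 groups, and the counts summed to 14107280, 14491500 and 16447199 read pairs in proximal replicates 1 to 3, 13581994, 13897386 and 15564808 in distal ones, and 14777216, 14287535 and 15870722 in monocultured ones. The columns carry a letter and a number, and no label states in words which letter is which gate. Here H was read as high labelling, L as low labelling and M as monocultured, and the sign of every proximal against distal difference rests on that reading.

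The cocultured and the monocultured libraries lay furthest apart. The first principal component held 65.5% of the variance and set the 3 monocultured libraries apart from the 6 cocultured ones, and the second, with 12.6%, set proximal apart from distal. A component with 7.58% of the variance split replicates inside groups, with proximal replicate 3 at one end and distal replicate 2 at the other, and its loadings followed the GC content of the genes (Spearman -0.64 across 14891 genes, which are not independent replicates).

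**Figure D1:**
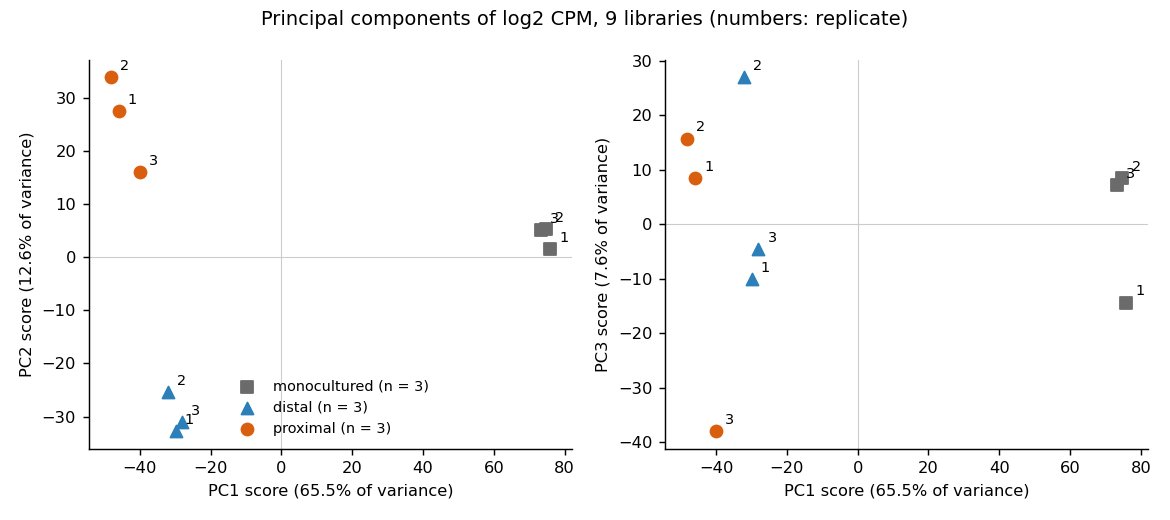
Scores of the 9 libraries on principal component 1 against components 2 and 3, from log2 CPM; each point is a library, with its group by colour and shape and its replicate number beside it. Component 1 (65.5%) parts monocultured from cocultured libraries, component 2 (12.6%) proximal from distal, and component 3 (7.6%) replicates within groups.

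ERBB2, the receptor by which the tumour cells were targeted (chromosome 17, 39687914 to 39730426, plus strand, GRCh38.p13), was measured first, because its reads in sorted macrophages bear on what the gates hold. It stood at 17.3 ± 2.03 CPM in proximal, 39.8 ± 7.76 in distal and 1.52 ± 0.348 in monocultured cells (mean ± SD, n = 3 in each group, here and for every CPM below). The log2 fold change was 3.50 ± 0.22 (± SE throughout) for proximal against monocultured, 4.71 ± 0.21 for distal against monocultured and -1.20 ± 0.16 for proximal against distal, and all 3 passed edgeR's test (adjusted p = 1.03e-08, 5.10e-10 and 1.85e-04). The summed level of the 28 listed markers of the tumour line, from which ERBB2 is left out, was highest in proximal cells, where ERBB2 was highest in distal ones. It was 2014 ± 182 CPM in proximal, 1146 ± 46.6 in distal and 1164 ± 34.8 in monocultured cells, with an exact permutation p of 0.1 for proximal against either other group, the smallest that 3 against 3 allows, and an exact p of 0.5 for distal against monocultured. NT5E, an ectonucleotidase, and LAMC1, a laminin chain, made up most of that sum and were abundant without any coculture (656 ± 41.2 and 263 ± 4.20 CPM in monocultured cells). The markers under 1 CPM in monoculture summed to 8.34 ± 0.838 CPM in proximal, 8.52 ± 0.733 in distal and 5.43 ± 0.564 in monocultured cells. Their exact permutation p was 0.1 for either gate against monoculture, log2 ratios 0.62 and 0.65, and 0.7 between the gates. These markers were chosen by their level in the same monocultured libraries, which favours a lower sum there. EGFR rose in both gates, from 2.36 ± 0.486 CPM in monocultured cells to 17.3 ± 0.666 in proximal and 17.6 ± 2.41 in distal ones. Keratins, structural proteins of epithelial cells, stayed near the floor: 6 of them summed to 0.834 ± 0.297 CPM in proximal, 1.96 ± 1.32 in distal and 1.64 ± 0.346 in monocultured cells, and KRT18 had 0 counts in all 9 libraries.

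The comparison of proximal with distal macrophages asks how cells sorted as near a tumour cell differed from cells of the same coculture sorted as far from one. The cytokine IL6 (chromosome 7, 22725884 to 22732002, plus strand) was at 46.5 ± 2.56 CPM in proximal and 19.8 ± 2.58 in distal cells, 2.34-fold higher. The neutrophil chemokine CXCL1 was 1.97-fold higher (889 ± 23.0 against 451 ± 19.7 CPM), and the interstitial collagenase MMP1 (chromosome 11, 102789919 to 102798160, minus strand) was 2.14-fold higher (849 ± 45.0 against 396 ± 16.5 CPM). In the other direction, proximal cells held 4.91-fold less MYB, a transcription factor of blood progenitors (chromosome 6, 135181308 to 135219173, plus strand; 16.6 ± 1.49 against 81.5 ± 10.1 CPM), 2.80-fold less of the mitotic kinase PLK1, and 3.12-fold less of the lipid receptor TREM2 (12.4 ± 0.348 against 38.8 ± 2.69 CPM). edgeR's quasi-likelihood test called 1296 genes higher and 1223 lower in proximal cells among 15427 tested, of which 99 and 517 changed at least 2-fold; 4578 genes had an unadjusted p under 0.05. Replicates of the 2 groups did not overlap for 4865 genes (31.5%, where chance gives 10%), among them 2449 of the 2519 called.

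These counts depend on single libraries and on the scaling. Without distal replicate 1, 816 genes were higher, and without distal replicate 3, 757 were higher and 768 lower; with upper-quartile scaling 34.2% of the calls were higher in proximal cells (816 higher, 1572 lower), against 51.4% with TMM and 61.2% with each library's GC trend removed (2733 higher, 1731 lower).

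The largest rises were moderate. SERPINB4, a serpin with a near-identical neighbour that could share its reads, rose by 1.88 ± 0.18 on the log2 scale, the endothelial glycoprotein MMRN2 by 1.51 ± 0.18, the cytokine IL11 by 1.46 ± 0.22 (5.48 ± 1.21 against 2.00 ± 0.352 CPM), the integrin activator FERMT2 by 1.42 ± 0.15, and the non-coding transcript LYPLAL1-AS1 by 1.38 ± 0.13. The chemokine genes CCL4 (1.88 ± 0.40), CCL4L2 (1.54 ± 0.26) and CCL3L3 (1.52 ± 0.21) were also among the 8 largest, but they are near-identical copies annotated on 3 sequences each, so their values are uncertain. Among the largest falls were RHEX, a regulator of erythroid expansion (-3.07 ± 0.20), MLC1, a membrane protein first known from astrocytes (-3.04 ± 0.21), the adaptor HSH2D (-2.88 ± 0.23), the laminin chain LAMA3 (-2.81 ± 0.20), the pentraxin NPTX1 (-2.73 ± 0.14; 20.2 ± 5.04 against 135 ± 4.52 CPM), the platelet receptor TREML1 (-2.64 ± 0.21), the haematopoietic factor GATA2 (-2.48 ± 0.15; 9.58 ± 2.22 against 53.6 ± 2.94 CPM) and PLPPR3 (-2.38 ± 0.20).

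Among the 28 gene lists, limma's camera test with a preset correlation of 0.01 called 7 higher and 4 lower in proximal cells, and 3 of the 11 held with an estimated correlation. Chemokines were one of these, with 10 of 15 measured members higher, 0 lower and 5 not called (10 and 0 adjusted over the list alone), and a median log2 change of 0.84. For chemokines camera gave adjusted p = 1.02e-06, and adjusted p = 0.0457 with an estimated correlation. CXCL3 (0.92 ± 0.08), CXCL2 (0.89 ± 0.09) and CCL20 (0.84 ± 0.08), all attractants of white cells, were examples. Matrix remodelling genes had 19 of 31 measured members higher, 5 lower and 7 not called (20 and 5 adjusted over the list alone), and a median of 0.39; the stromelysin MMP10 (1.18 ± 0.09), the neutrophil collagenase MMP8 (1.31 ± 0.12) and the urokinase PLAU (1.00 ± 0.09) rose. For matrix remodelling genes camera gave adjusted p = 4.98e-06, and adjusted p = 0.0457 with an estimated correlation. The NF-kappaB and TNF response list had 14 of 25 measured members higher, 2 lower and 9 not called (14 and 3 adjusted over the list alone), with a median of 0.38. For NF-kappaB and TNF response camera gave adjusted p = 1.34e-04, and adjusted p = 0.153 with an estimated correlation. Its member IL1B, which encodes interleukin-1 beta, was the most abundant transcript in 5 of the 6 cocultured libraries and rose from 14932 ± 498 CPM in distal to 23639 ± 645 in proximal cells.

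The other 4 rising lists, like that of NF-kappaB, were called only with the preset correlation. Hypoxia and glycolysis genes had 17 of 27 measured members higher, 0 lower and 10 not called (18 and 0 adjusted over the list alone), with rises of the hexokinase HK2 (0.70 ± 0.07), the mitophagy receptor BNIP3 (0.59 ± 0.09) and the glycolytic enzyme PGK1 (0.38 ± 0.07). For hypoxia and glycolysis genes camera gave adjusted p = 1.65e-07, and adjusted p = 0.198 with an estimated correlation. Angiogenic and growth factors had 6 of 23 measured members higher, 1 lower and 16 not called (7 and 2 adjusted over the list alone), with the activin subunit INHBA (0.85 ± 0.09), the EGF-receptor ligand HBEGF (0.67 ± 0.07) and VEGFC (0.92 ± 0.11) up and the stress cytokine GDF15 down (-1.03 ± 0.12). For angiogenic and growth factors camera gave adjusted p = 0.00222, and adjusted p = 0.239 with an estimated correlation. Tumour-associated macrophage genes had 9 of 22 measured members higher, 3 lower and 10 not called (9 and 3 adjusted over the list alone): osteopontin, SPP1, rose (0.76 ± 0.09), as did the checkpoint ligand CD274 (1.03 ± 0.13), while TREM2 fell (-1.64 ± 0.11). That list's call was lost without proximal replicate 3 (camera adjusted p = 0.0968), distal replicate 2 (0.0608) or distal replicate 3 (0.0541) and held in 6 of the 9 runs that left out a library (camera adjusted p from 0.0334 to 0.0968). For tumour-associated macrophage genes camera gave adjusted p = 0.0432, and adjusted p = 0.153 with an estimated correlation. Tumour cell markers had 6 of 21 measured members higher, 2 lower and 13 not called (6 and 2 adjusted over the list alone); NT5E (0.93 ± 0.10), LAMC1 (0.81 ± 0.07), CAV1 (1.01 ± 0.15) and YAP1 (0.89 ± 0.13) rose. The summed level of the 28 markers, 2014 against 1146 CPM, was carried by NT5E and LAMC1, and the sum of those low in monoculture was 8.34 CPM in proximal against 8.52 in distal cells (exact permutation p = 0.7). For breast tumour cell markers (MDA-MB-231) camera gave adjusted p = 0.0136, and adjusted p = 0.153 with an estimated correlation.

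Proliferation genes fell in proximal against distal cells: 0 of 24 measured members higher, 22 lower and 2 not called (0 and 23 adjusted over the list alone), with a median log2 change of -0.86. For proliferation genes camera gave adjusted p = 3.64e-15, and adjusted p = 0.0457 with an estimated correlation. The survivin gene BIRC5 (-1.40 ± 0.12), the kinetochore gene CENPF (-1.45 ± 0.15) and MKI67, which encodes the Ki-67 antigen (-0.97 ± 0.11; 47.7 ± 7.82 against 93.1 ± 5.68 CPM), were examples. Undifferentiated monocyte and granule genes had 0 of 8 measured members higher, 4 lower and 4 not called (0 and 4 adjusted over the list alone), with falls of MYB (-2.30 ± 0.12), the cytokine receptor FLT3 (-2.20 ± 0.22) and the myeloid factor CEBPA (-1.22 ± 0.26). For undifferentiated monocyte and granule genes camera gave adjusted p = 1.34e-04, and adjusted p = 0.0509 with an estimated correlation. Type I interferon response genes had 1 of 33 measured members higher, 10 lower and 22 not called (1 and 13 adjusted over the list alone), among them CMPK2 (-1.29 ± 0.19) and the antiviral genes RSAD2 (-1.26 ± 0.26) and MX2 (-0.98 ± 0.21). For type I interferon response camera gave adjusted p = 5.01e-04, and adjusted p = 0.153 with an estimated correlation. Immediate early and dissociation genes had 2 of 25 measured members higher, 12 lower and 11 not called (4 and 14 adjusted over the list alone), with the nuclear receptors NR4A1 (-1.81 ± 0.22) and NR4A2 (-1.27 ± 0.17) and the factor KLF4 (-1.22 ± 0.14) lower. For immediate early and dissociation genes camera gave adjusted p = 7.10e-04, and adjusted p = 0.398 with an estimated correlation.

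**Figure D2:**
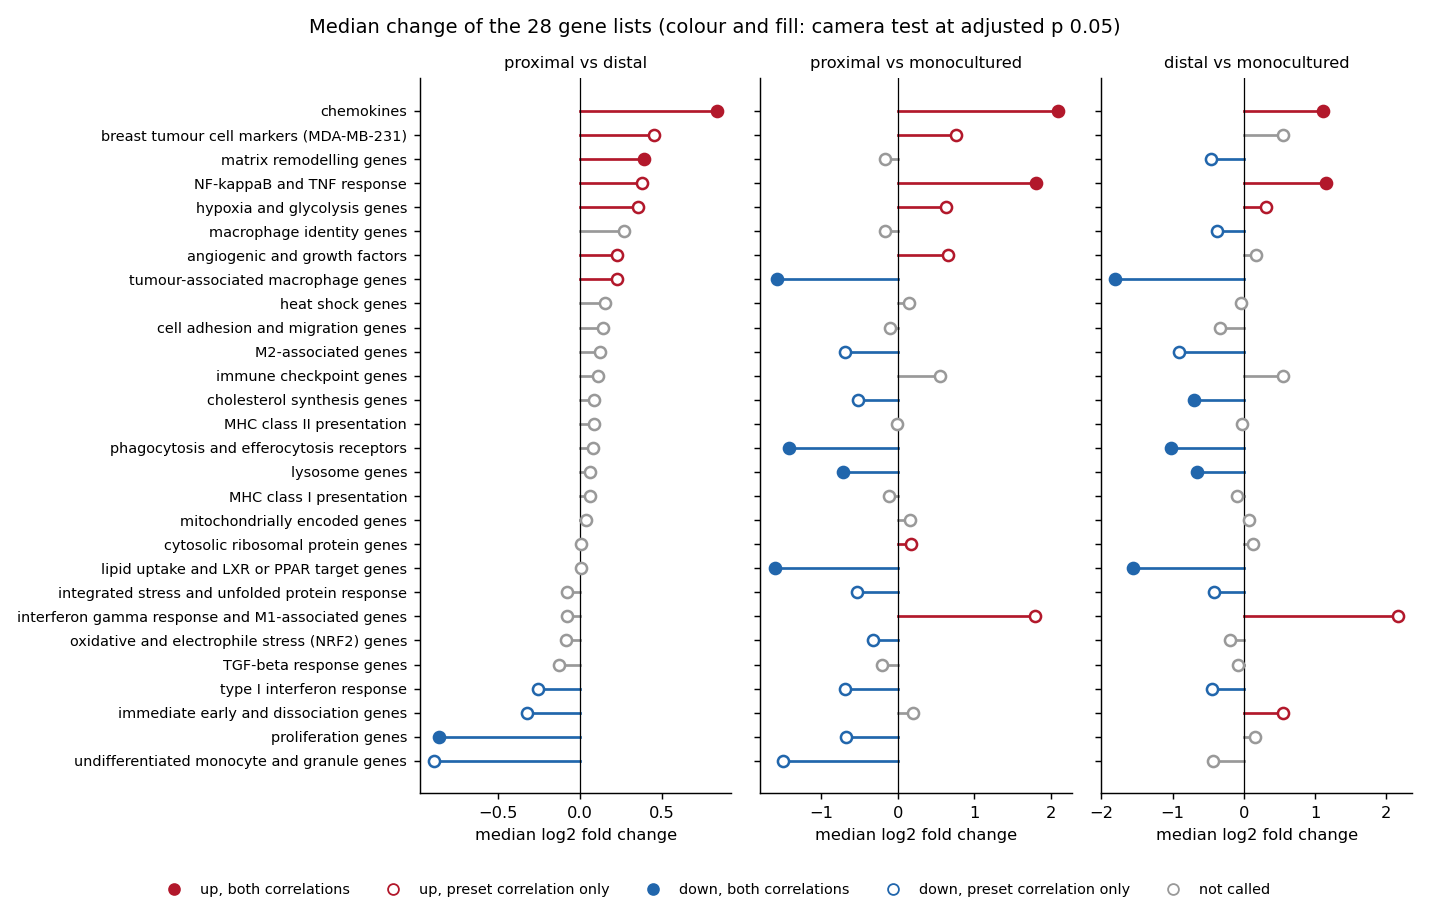
Median log2 fold change of the measured members of each of the 28 gene lists in the 3 comparisons, each panel with its own horizontal range; red and blue mark lists called up and down by camera, filled points those that also hold with an estimated correlation, and grey those not called. Chemokines were up and filled in all 3 panels, and proliferation genes were down and filled for proximal against distal alone.

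The comparison of proximal with monocultured macrophages asks how cocultured cells sorted as near a tumour cell differed from macrophages kept alone. Transcripts that were nearly absent in monoculture became abundant. IL12B, the shared subunit of interleukins 12 and 23 (chromosome 5, 159314780 to 159330487, minus strand), was at 126 ± 6.16 CPM in proximal cells against 1 count over the 3 monocultured libraries, a ratio of 5576 (95% counting interval 1000.3 to 220266), and IL6 rose by 8.88 ± 0.29 on the log2 scale. PTGS2, the inducible cyclooxygenase, rose 41.9-fold and CD274, the ligand of the checkpoint receptor PD-1, 35.9-fold (52.9 ± 8.47 against 1.46 ± 0.130 CPM). Genes of lipid-handling macrophages went down: the lipoprotein lipase LPL was 11.2-fold lower (33.4 ± 4.81 against 374 ± 30.4 CPM) and the fatty acid carrier FABP4 19.8-fold lower. edgeR's test called 3455 genes higher and 3565 lower, 1324 and 1587 of them by at least 2-fold; 8083 genes had an unadjusted p under 0.05, and replicates did not overlap for 8166 (52.9%, where chance gives 10%), among them 6749 of the 7020 called.

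The remaining large rises were also against counts near 0. SERPINB7, STAT4 and SERPINA9 had 0 counts in monoculture and were at least 285-, 151- and 110.3-fold higher, against a floor of 3 counts over the group; STAT4 transmits interleukin-12 signals. The tryptophan-degrading enzyme IDO1 had 2 counts in monoculture (ratio 1653, 95% counting interval 457 to 13656), RIPOR2 had 1 (ratio 2098, interval 376 to 82892) and SERPINB4 had 1 (ratio 712, interval 127 to 28165). Intervals and floors cover counting error only. The largest falls were of the metalloproteinases ADAMTS8 (-6.67 ± 0.29) and ADAMTS15 (-5.25 ± 0.35), the monocyte chemokine receptor CCR2 (-6.44 ± 0.36), the lipid hydroxylase FA2H (-5.83 ± 0.32), DMBX1 (-5.83 ± 0.37), the neuropeptide receptor VIPR1 (-5.56 ± 0.39), the small heat shock protein HSPB7 (-5.29 ± 0.19) and the gluconeogenic enzyme FBP1 (-5.19 ± 0.20).

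Camera called 7 lists higher and 11 lower in proximal than in monocultured cells, and 6 of the 18 held with an estimated correlation. Some of the 6 share members and are not separate results. CXCL1, CXCL2 and CXCL3 are in both the chemokine and the NF-kappaB list. LPL and FABP4 are in both the tumour-associated macrophage and the lipid list, and CD36 and MSR1 in both the lipid and the phagocytosis list. Chemokines had 14 of 15 measured members higher, 0 lower and 1 not called (14 and 0 adjusted over the list alone), with a median of 2.09, which stayed at 2.09 with the member at 0 counts in monoculture set at its bound; CCL1 (6.97 ± 0.17) and CXCL1 (3.98 ± 0.10) rose. For chemokines camera gave adjusted p = 1.51e-09, and adjusted p = 0.0132 with an estimated correlation. NF-kappaB and TNF response genes had 23 of 25 measured members higher, 1 lower and 1 not called (23 and 1 adjusted over the list alone), with a median of 1.81, among them the superoxide dismutase SOD2 (2.91 ± 0.07). For NF-kappaB and TNF response camera gave adjusted p = 5.73e-13, and adjusted p = 0.0154 with an estimated correlation. The list of interferon gamma response and M1-associated genes had 13 of 21 measured members higher, 5 lower and 3 not called (13 and 6 adjusted over the list alone). IL12B, IL6, IL23A (6.48 ± 0.15) and PTGS2 (5.39 ± 0.14) were among those that rose. For interferon gamma response and M1-associated genes camera gave adjusted p = 2.00e-04, and adjusted p = 0.139 with an estimated correlation. Hypoxia and glycolysis genes had 22 of 27 measured members higher, 0 lower and 5 not called (22 and 0 adjusted over the list alone), with BNIP3 (2.56 ± 0.10) and the glucose transporter SLC2A1 (1.84 ± 0.09) up. For hypoxia and glycolysis genes camera gave adjusted p = 7.09e-08, and adjusted p = 0.132 with an estimated correlation. Angiogenic and growth factors had 12 of 23 measured members higher, 4 lower and 7 not called (12 and 4 adjusted over the list alone): THBS1 (4.24 ± 0.14), which restrains vessel growth, and INHBA (2.58 ± 0.09) rose, and the macrophage growth factor CSF1 fell (-2.62 ± 0.11). For angiogenic and growth factors camera gave adjusted p = 0.0141, and adjusted p = 0.246 with an estimated correlation. Tumour cell markers had 11 of 21 measured members higher, 2 lower and 8 not called (11 and 2 adjusted over the list alone). For breast tumour cell markers (MDA-MB-231) camera gave adjusted p = 0.00734, and adjusted p = 0.0941 with an estimated correlation. Ribosomal protein genes had 11 of 37 measured members higher, 0 lower and 26 not called (10 and 0 adjusted over the list alone), for example RPS20 (0.58 ± 0.07); that call held in 7 of the 9 runs that left out a library and was lost without proximal replicate 3 (camera adjusted p = 0.157) or monocultured replicate 2 (0.0670; range over the 9 runs 0.00734 to 0.157). For cytosolic ribosomal protein genes camera gave adjusted p = 0.0208, and adjusted p = 0.480 with an estimated correlation.

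Of the 11 lists that fell, 4 held with an estimated correlation. Tumour-associated macrophage genes had 3 of 22 measured members higher, 18 lower and 1 not called (3 and 19 adjusted over the list alone), with a median of -1.58, with TREM2 (-2.74 ± 0.11) and the lysosomal lipase LIPA (-2.89 ± 0.12) lower and CD274 (5.17 ± 0.17) higher. For tumour-associated macrophage genes camera gave adjusted p = 1.85e-07, and adjusted p = 0.0132 with an estimated correlation. Lipid uptake and LXR or PPAR target genes had 2 of 23 measured members higher, 17 lower and 4 not called (2 and 17 adjusted over the list alone), including the oxysterol receptor NR1H3 (-2.72 ± 0.09) and the scavenger receptor CD36 (-3.88 ± 0.17). For lipid uptake and LXR or PPAR target genes camera gave adjusted p = 8.27e-07, and adjusted p = 0.0132 with an estimated correlation. Phagocytosis and efferocytosis receptors had 2 of 22 measured members higher, 15 lower and 5 not called (2 and 15 adjusted over the list alone), including the integrin ITGAM (-3.07 ± 0.09) and the apoptotic cell receptor MERTK (-2.74 ± 0.14). For phagocytosis and efferocytosis receptors camera gave adjusted p = 4.95e-06, and adjusted p = 0.0132 with an estimated correlation. Lysosome genes had 0 of 27 measured members higher, 22 lower and 5 not called (0 and 23 adjusted over the list alone), including cathepsin L, CTSL (-1.71 ± 0.09). For lysosome genes camera gave adjusted p = 1.12e-07, and adjusted p = 0.0406 with an estimated correlation.

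A further 7 lists fell only with the preset correlation. Proliferation genes had 0 of 24 measured members higher, 21 lower and 3 not called (0 and 22 adjusted over the list alone), such as RRM2 (-1.44 ± 0.11). For proliferation genes camera gave adjusted p = 8.27e-07, and adjusted p = 0.0828 with an estimated correlation. Type I interferon response genes had 2 of 33 measured members higher, 23 lower and 8 not called (2 and 25 adjusted over the list alone), such as OAS3 (-1.21 ± 0.10). For type I interferon response camera gave adjusted p = 7.33e-06, and adjusted p = 0.0651 with an estimated correlation. Integrated stress and unfolded protein response genes had 4 of 26 measured members higher, 17 lower and 5 not called (4 and 19 adjusted over the list alone), such as the serine synthesis gene PHGDH (-2.41 ± 0.16). For integrated stress and unfolded protein response camera gave adjusted p = 3.43e-04, and adjusted p = 0.155 with an estimated correlation. Undifferentiated monocyte and granule genes had 1 of 8 measured members higher, 6 lower and 1 not called (1 and 7 adjusted over the list alone). For undifferentiated monocyte and granule genes camera gave adjusted p = 0.00472, and adjusted p = 0.0751 with an estimated correlation. Cholesterol synthesis genes had 2 of 24 measured members higher, 14 lower and 8 not called (2 and 14 adjusted over the list alone). For cholesterol synthesis genes camera gave adjusted p = 0.00291, and adjusted p = 0.0751 with an estimated correlation. M2-associated genes had 6 of 19 measured members higher, 12 lower and 1 not called (6 and 12 adjusted over the list alone), with a median of -0.69, and -0.69 with the member at 0 counts at its bound. For M2-associated genes camera gave adjusted p = 0.00622, and adjusted p = 0.0751 with an estimated correlation. Oxidative and electrophile stress genes had 2 of 23 measured members higher, 11 lower and 10 not called (2 and 11 adjusted over the list alone), such as the haem oxygenase HMOX1 (-2.44 ± 0.14). For oxidative and electrophile stress (NRF2) genes camera gave adjusted p = 0.0206, and adjusted p = 0.155 with an estimated correlation.

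The comparison of distal with monocultured macrophages asks how cocultured cells with little of the proximity label differed from macrophages kept alone. IL12B was again induced, at 73.7 ± 5.00 CPM against 1 count over the 3 monocultured libraries (ratio 3259, 95% counting interval 584 to 128751), and IL6 rose by 7.65 ± 0.31 on the log2 scale. The collagen receptor subunit ITGA1 rose 37.7-fold (244 ± 22.7 against 6.47 ± 0.200 CPM) and IL23A 77.7-fold. LPL was 7.76-fold lower (48.2 ± 5.57 against 374 ± 30.4 CPM) and FABP4 38.1-fold lower. edgeR's test called 3201 genes higher and 3344 lower, 1368 and 1159 of them by at least 2-fold; 7704 genes had an unadjusted p under 0.05, and replicates did not overlap for 8346 (54.1%, where chance gives 10%), among them 6413 of the 6545 called. The majority direction depends on the scaling: with upper-quartile factors 3793 genes were higher and 2834 lower (57.2% higher, against 48.9% with TMM).

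Among the largest rises, STAT4, SERPINB7 and the dendritic cell chemokine CCL19 had 0 counts in monoculture and were at least 173-, 115- and 76.8-fold higher against the same floor of 3 counts over the group. IDO1 and LAMP3, a marker of mature dendritic cells, had 2 counts each (ratios 917, interval 254 to 7578, and 241, interval 66.2 to 1991), and RIPOR2 had 1 (ratio 990.1, interval 177 to 39145). The largest falls were of ADAMTS8 (-6.13 ± 0.27), FABP4 (-5.25 ± 0.20), FBP1 (-5.09 ± 0.20), MTUS1 (-4.99 ± 0.22), HSPB7 (-4.89 ± 0.18), ADAMTS15 (-4.69 ± 0.33), ATP1B4 (-4.61 ± 0.33) and the potassium channel KCNJ1 (-4.39 ± 0.25).

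Camera called 5 lists higher and 10 lower in distal than in monocultured cells, and 7 of the 15 held with an estimated correlation. NF-kappaB and TNF response genes had 22 of 25 measured members higher, 1 lower and 2 not called (22 and 1 adjusted over the list alone). For NF-kappaB and TNF response camera gave adjusted p = 7.16e-12, and adjusted p = 0.0191 with an estimated correlation. The feedback inhibitor TNFAIP3 (1.79 ± 0.07) rose. Chemokines had 12 of 15 measured members higher, 0 lower and 3 not called (13 and 0 adjusted over the list alone). For chemokines camera gave adjusted p = 6.25e-08, and adjusted p = 0.0191 with an estimated correlation. Their median was 1.11, and 1.11 with the member at 0 counts at its bound. The other 5 that held went down. Tumour-associated macrophage genes had 2 of 22 measured members higher, 20 lower and 0 not called (2 and 20 adjusted over the list alone). For tumour-associated macrophage genes camera gave adjusted p = 5.32e-10, and adjusted p = 0.00848 with an estimated correlation. Lipid uptake and LXR or PPAR target genes had 3 of 23 measured members higher, 17 lower and 3 not called (3 and 17 adjusted over the list alone). For lipid uptake and LXR or PPAR target genes camera gave adjusted p = 1.25e-07, and adjusted p = 0.00848 with an estimated correlation. The scavenger receptor CD36 (-3.87 ± 0.17) fell. Phagocytosis and efferocytosis receptors had 2 of 22 measured members higher, 16 lower and 4 not called (2 and 16 adjusted over the list alone). For phagocytosis and efferocytosis receptors camera gave adjusted p = 1.63e-07, and adjusted p = 0.00848 with an estimated correlation. Among them MSR1 (-3.68 ± 0.14), a receptor of modified lipoproteins, fell. Lysosome genes had 0 of 27 measured members higher, 22 lower and 5 not called (0 and 22 adjusted over the list alone). For lysosome genes camera gave adjusted p = 2.85e-09, and adjusted p = 0.0242 with an estimated correlation. Cathepsin L, CTSL (-2.12 ± 0.09), fell. Cholesterol synthesis genes had 1 of 24 measured members higher, 16 lower and 7 not called (1 and 18 adjusted over the list alone). For cholesterol synthesis genes camera gave adjusted p = 2.50e-05, and adjusted p = 0.0242 with an estimated correlation.

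The other 8 lists were called with the preset correlation alone, 3 of them higher. Interferon gamma response and M1-associated genes had 13 of 21 measured members higher, 5 lower and 3 not called (14 and 5 adjusted over the list alone). For interferon gamma response and M1-associated genes camera gave adjusted p = 1.11e-05, and adjusted p = 0.113 with an estimated correlation. Hypoxia and glycolysis genes had 15 of 27 measured members higher, 4 lower and 8 not called (15 and 4 adjusted over the list alone). For hypoxia and glycolysis genes camera gave adjusted p = 0.00152, and adjusted p = 0.349 with an estimated correlation. Immediate early and dissociation genes had 16 of 25 measured members higher, 4 lower and 5 not called (16 and 4 adjusted over the list alone). For immediate early and dissociation genes camera gave adjusted p = 0.00395, and adjusted p = 0.418 with an estimated correlation. In this list NR4A2 (3.40 ± 0.20) and SOCS3 (2.34 ± 0.16) rose, and EGR2 (-1.96 ± 0.09) fell. The other 5 were lower. Matrix remodelling genes had 7 of 31 measured members higher, 15 lower and 9 not called (8 and 15 adjusted over the list alone). For matrix remodelling genes camera gave adjusted p = 0.00817, and adjusted p = 0.111 with an estimated correlation. The protease inhibitor TIMP3 (-2.66 ± 0.10) fell. M2-associated genes had 5 of 19 measured members higher, 10 lower and 4 not called (5 and 10 adjusted over the list alone). For M2-associated genes camera gave adjusted p = 0.00643, and adjusted p = 0.0762 with an estimated correlation. Their median was -0.92, and -0.92 with the member at 0 counts at its bound. The transglutaminase TGM2 (-2.25 ± 0.10) fell. Macrophage identity genes had 4 of 17 measured members higher, 9 lower and 4 not called (4 and 9 adjusted over the list alone). For macrophage identity genes camera gave adjusted p = 0.0313, and adjusted p = 0.150 with an estimated correlation. The haemoglobin receptor CD163 (-3.44 ± 0.17) fell. Type I interferon response genes had 3 of 33 measured members higher, 19 lower and 11 not called (3 and 21 adjusted over the list alone). For type I interferon response camera gave adjusted p = 0.00315, and adjusted p = 0.150 with an estimated correlation. The antiviral gene IFIT1 (-1.51 ± 0.18) fell. Integrated stress and unfolded protein response genes had 2 of 26 measured members higher, 14 lower and 10 not called (2 and 14 adjusted over the list alone). For integrated stress and unfolded protein response camera gave adjusted p = 0.00107, and adjusted p = 0.218 with an estimated correlation. The serine synthesis gene PSAT1 (-2.17 ± 0.15) fell. Proliferation genes were not called as a list in distal against monocultured cells, with 6 of 24 measured members higher, 3 lower and 15 not called (3 and 2 adjusted over the list alone). Their camera adjusted p was 0.317. Ribosomal protein genes had 10 of 37 measured members higher, 0 lower and 27 not called (6 and 0 adjusted over the list alone) and missed the threshold (camera adjusted p = 0.0519). They passed it with DESeq2 size factors (camera adjusted p = 0.0480) and in 3 of the 9 runs that left out a library: without distal replicate 2 (0.0223), monocultured replicate 1 (0.0216) or proximal replicate 3 (0.0343), with a range of 0.0216 to 0.174.

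**Figure D3:**
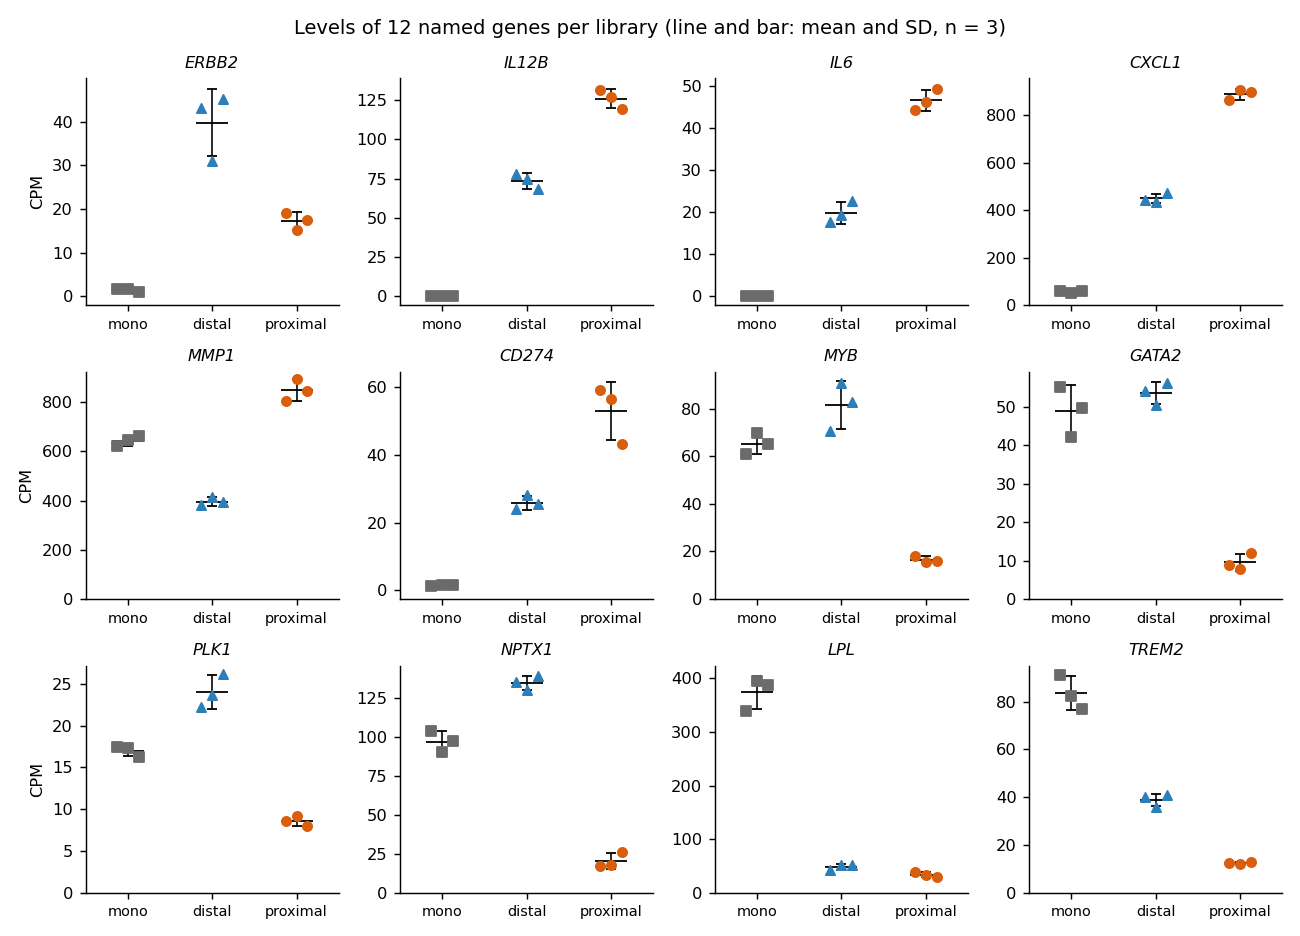
CPM of 12 named genes in each of the 9 libraries, with a linear axis for each gene; points are libraries, and the line and bar are the mean and SD of 3 libraries. ERBB2 was highest in distal cells (39.8 CPM), MYB and PLK1 were lowest in proximal cells (16.6 and 8.59 CPM), and IL12B and IL6 were near 0 in monoculture.

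Many genes differed from monoculture in the same direction in both gates. Whether monocultured cells were labelled and sorted alike is not given in the sources used here, so a part shared by both gates is not set apart from labelling and sorting. Across the 15427 genes the log2 changes of proximal and distal cells against monoculture had a Pearson r of 0.884, where unchanged groups that share the 3 control libraries gave 0.498 on average in 100 simulated sets (the central 95% of sets reached up to 0.520); genes are not independent replicates. The covariance was 0.948 against a simulated 0.0330, a difference of 0.915. IL12B, IL6 and ITGA1 were among 2369 genes called higher in both gates (717 for independent lists), and LPL, CD36 and FBP1 among 2497 called lower in both (773 for independent lists). Only 73 genes were called in opposite directions (1489 for independent lists). Of these, 27, MMP1 among them, were higher in proximal and lower in distal cells. The other 46, MYB among them, were lower in proximal and higher in distal cells. All 73 were also called between the gates. That is nearly given by the opposite calls, since the difference between the gates adds the 2 effects. The 3 controls cannot be split into groups of 2. The simulated sets shared the controls and put the part of the covariance from their replicate spread at 0.0330. The numbers for independent lists take no account of the shared controls, so part of the excess over those numbers may come from the sharing.

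**Figure D4:**
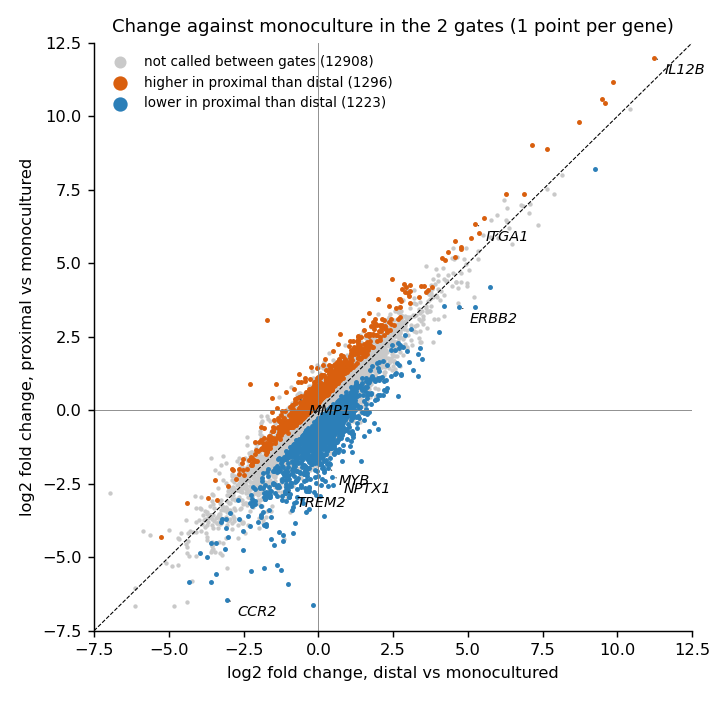
Log2 fold change of proximal (vertical) against that of distal macrophages (horizontal), each relative to monoculture, for the 15427 genes tested; orange and blue points are the 1296 and 1223 genes called higher and lower in proximal than in distal cells. Most points lie along the dashed line of equal change, and genes such as MYB, NPTX1 and MMP1 lie in the quadrants of opposite change.

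Camera called 7 of the 28 lists in none of the 3 comparisons with all libraries. Of these, immune checkpoint genes gained a call for proximal against monocultured cells without monocultured replicate 1, proximal replicate 1 or proximal replicate 2 (camera adjusted p = 0.0331, 0.0444 and 0.0182), and for distal against monocultured cells without monocultured replicate 1 (0.0460). For proximal against monocultured cells, cell adhesion and migration genes had 9 of 32 measured members higher, 13 lower and 10 not called (9 and 13 adjusted over the list alone), with ITGA1 up (6.32 ± 0.15); immune checkpoint genes had 10 of 21 measured members higher, 5 lower and 6 not called (10 and 5 adjusted over the list alone), with CD80 up (4.48 ± 0.22); TGF-beta response genes had 7 of 23 measured members higher, 10 lower and 6 not called (8 and 11 adjusted over the list alone), with ID1 up (2.85 ± 0.16) and TSC22D1 down (-1.27 ± 0.07). Heat shock genes had 4 of 17 measured members higher, 1 lower and 12 not called (4 and 1 adjusted over the list alone), mitochondrially encoded genes 3 of 13 measured members higher, 0 lower and 10 not called (0 and 0 adjusted over the list alone), MHC class I genes 2 of 13 measured members higher, 3 lower and 8 not called (2 and 3 adjusted over the list alone) and MHC class II genes 2 of 8 measured members higher, 2 lower and 4 not called (2 and 2 adjusted over the list alone), with CD74, the class II invariant chain, down (-0.85 ± 0.09). Among MHC class II genes the median and the mean differed in sign in each comparison (medians 0.08, -0.01 and -0.03 and means -0.08, 0.05 and 0.13 in the order above), and camera's direction followed the mean. Medians and means also parted for adhesion genes (0.14 and -0.05) and phagocytosis receptors (0.08 and -0.04) between the gates, both up by camera, and for heat shock genes (-0.04 and 0.07, down by camera) between distal and monocultured cells. Several MHC genes have copies on other sequences of the annotation, which lowers their counts.

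A p-value here compares the libraries of each group. The labels say only that the work was done in triplicate, and nothing says that replicates are separate cultures, so the p-values may measure technical spread.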

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

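The 14 genes below are the named genes called in opposite directions in the 2 gates against monoculture, and the tests of explanations in this part were chosen after the result was seen. For each, the difference between the 2 effects is the proximal against distal comparison in edgeR, and a call there was a condition for being listed. The difference stayed called in all 9 runs that left out a library. These runs share most of their libraries, so they are not independent tests. The genes listed are 14 of the 73 called in opposite directions, and no class of genes was tested among the 73.

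Of the 14, 7 were higher in proximal and lower in distal than in monocultured cells. The log2 difference between the gates was 1.10 for the collagenase MMP1, 1.18 for the stromelysin MMP10, 1.00 for the urokinase PLAU, 0.76 for osteopontin (SPP1), 0.77 for the integrin chain ITGB1, 1.42 for the integrin activator FERMT2 and 0.70 for the hexokinase HK2. The other 7 were lower in proximal and higher in distal cells. The difference was -1.49 for PLK1, -1.40 for BIRC5, -1.45 for CENPF, -0.97 for MKI67, -2.30 for MYB, -1.22 for KLF4 and -2.73 for the pentraxin NPTX1. The opposite calls held in all 9 runs for HK2, MKI67, MMP1, MMP10, NPTX1, PLK1 and SPP1. They held in 3 of 9 for BIRC5 (lost without proximal 1, distal 1 or 3, or any monocultured library) and for ITGB1 (lost without proximal 1 or 2, distal 3 or any monocultured library). They held in 4 of 9 for CENPF (lost without proximal 1, distal 2 or 3, or monocultured 1 or 3) and for FERMT2 (lost without any distal library or monocultured 2 or 3). They held in 5 of 9 for MYB (lost without distal 2 or 3 or monocultured 1 or 3), 6 for PLAU (lost without proximal 3 or monocultured 1 or 2) and 7 for KLF4 (lost without distal 3 or monocultured 3).

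For the lower proliferation genes in proximal than in distal cells, tumour cells in the distal gate alone would raise distal levels and leave proximal ones near monoculture. Instead 21 of the 24 members were called lower in proximal than in monocultured cells, a fall that tumour cells in the distal gate do not account for. The difference between the gates is not decided by this. If coculture lowered these genes in both gates, tumour cell RNA could raise them again in the distal gate and give the same count. The small difference of distal from monocultured cells, with 6 members higher and 3 lower and a camera adjusted p of 0.317 for the list, stays open to them. Cell states present before the sort may also have been separated by it: for 17 of the 24 members the monocultured level lay between those of the gates. The design confounds such states with the gate, so this and a response of macrophages to nearby tumour cells cannot be told apart.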

How the results depend on the processing

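The alternatives that remove the GC trend, keep countable genes, or leave out proximal replicate 3 with distal replicate 2 were chosen after seeing the data. No call of the 3 comparisons reversed in any setting. Of 3141 values of named genes with a library left out, 3034 kept direction and side of the threshold, 95 lost the call and 12 gained one. In the other settings these were 4323, 140 and 32 of 4495. Named genes were chosen mostly for large changes or small p, which favours keeping their calls. Of all 2519 calls between proximal and distal cells, 59.7% to 91.5% were kept with a library left out. The lowest share was without distal replicate 3. With only the 2 groups fitted, 72.1% of those tested were kept. Against monoculture, 82.2% to 98.7% of the proximal and 81.2% to 99.8% of the distal calls were kept with a library left out. Genes higher in proximal than in distal cells numbered 816 (1572 lower) with upper-quartile factors, 815 (994 lower) with only the 2 groups fitted, 2733 (1731 lower) with the GC trend removed, and 2733 (with 2253 lower) with proximal replicate 3 and distal replicate 2 left out, which lowers the spread by construction. The cause of the first 2 was not tested. With glmTreat, which asks for more than a 1.5-fold change, 80 were higher and 212 lower, against 1275 and 1575 for proximal and 1193 and 1198 for distal against monocultured cells. With each library left out in turn, proximal against distal gave 757 to 1897 higher (816 without distal replicate 1, 757 without distal replicate 3) and 768 to 1558 lower (768 without distal replicate 3). Proximal against monocultured gave 2907 to 3836 higher and 3061 to 3981 lower, and distal against monocultured 2686 to 3712 and 2776 to 3786. Lists called were 3, 6 and 7 with an estimated correlation and 25 for distal against monocultured with fry; the cause was not tested. The r of the 2 changes against monoculture ranged from 0.851 to 0.911. With replicate number as a block, 1371 and 1249, 3497 and 3671, and 3252 and 3461 genes were called. Correlations of the deviations from group means ran from -0.159 to 0.296 for same-numbered libraries and from -0.419 to 0.300 for differently numbered ones. These deviations also follow GC content, so the correlations cannot decide whether the numbers pair the samples. At this depth, spread and number of libraries, and with 200 of 15067 genes changed, 29.9% of simulated 1.5-fold changes were recovered. The real comparison of the gates called 2519 of 15427 genes. The adjusted threshold depends on the share of changed genes, so recovery there may differ. What limits recovery was not tested.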

Other observations

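The tests of the ERBB2 pattern, of GC content on the calls between the gates and of the other splits were chosen after the result was seen; that of GC content on the split with 920 genes was set before its result. Among lists that camera did not call between the gates, 4 with members called in both directions are given here, chosen after their values were seen. Limma's fry, whose directional p tests whether genes move one way, called 2 of the 4 up. Phagocytosis and efferocytosis receptors had 5 members higher and 4 lower in proximal cells, with the integrin chain ITGB3 (0.96 ± 0.08) and the scavenger receptor LRP1 (0.64 ± 0.08) up and the apoptotic cell receptor AXL down (-1.46 ± 0.19) (fry adjusted p = 0.0569, camera adjusted p = 0.741). Macrophage identity genes had 8 higher and 4 lower, with the endotoxin co-receptor CD14 (0.59 ± 0.10) and the haemoglobin receptor CD163 (1.06 ± 0.19) up and the antibody receptor FCGR1A (-1.21 ± 0.16) and CD4 (-0.53 ± 0.09) down (fry adjusted p = 0.0508, camera adjusted p = 0.324). M2-associated genes had 6 higher and 2 lower, with the interleukin-1 antagonists IL1RN (0.63 ± 0.07) and IL1R2 (1.06 ± 0.13) up and VSIG4 (-1.55 ± 0.24) and ALOX15 (-2.62 ± 0.47) down (fry adjusted p = 0.0106, camera adjusted p = 0.314). Adhesion and migration genes had 13 higher and 5 lower, with the integrin chains ITGA1 (1.09 ± 0.12) and ITGB1 (0.77 ± 0.10) up and CCR2 down (-3.37 ± 0.49) (fry adjusted p = 0.0172, camera adjusted p = 0.314).

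ERBB2 was higher in both gates than in monoculture, and higher in distal than in proximal cells. Tumour cells or their RNA in both gates may account for the first, since the sort was on the biotin label. Tumour markers that are low in monoculture summed to 8.34 CPM in proximal and 8.52 in distal against 5.43 in monocultured cells. They were chosen by their level in the same monocultured libraries, which favours a lower sum there. That sum thus cannot decide the question. All listed markers without ERBB2 summed to 2014 CPM in proximal, 1146 in distal and 1164 in monocultured cells. The exact permutation p against monoculture was 0.1 for proximal and 0.5 for distal cells. NT5E and LAMC1, abundant without coculture, made up most of this larger sum. The summed level of 6 keratins was -0.802 CPM in proximal less monocultured cells and 0.326 CPM in distal less monocultured cells, the latter within the SD of 1.32 in distal cells. The ratio of ERBB2 to keratins in these tumour cells is not in the data, so this stays open. A larger share of tumour cell RNA in the distal gate would raise all tumour markers alike, and it stays open for ERBB2 being higher there. Over the 7 markers called higher than monoculture in both gates, the median log2 ratio of the distal to the proximal rise was -0.70. The SD across the 7 markers was 0.720, and 1 of 7 was larger in distal. The ratio for ERBB2 was 1.28. Its spread of 0.346 is another measure, the replicate variances of log2 CPM in the 2 gates combined, without monoculture. The set of 7 leaves out the matricellular genes CCN1 and CCN2, the 2 markers called higher in distal than in both other groups. These 2 are named here after their values were seen. CCN1 was at 5.10 CPM in distal, 2.94 in proximal and 3.34 in monocultured cells (edgeR adjusted p = 0.0263 between the gates), and CCN2 at 1.03, 0.353 and 0.207 CPM (adjusted p = 0.0427). The markers thus moved both ways. Macrophages express some of these markers themselves, and a change of ERBB2 in the macrophages, or transfer of its RNA, stays open and was not tested.

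GC content split replicates within groups, with a correlation between GC and a library's deviation from its group from -0.574 in distal replicate 2 to 0.602 in proximal replicate 3. With each library's GC trend removed, 99.3% of the calls between proximal and distal cells that have a GC value stayed past the threshold in the same direction, which argues against GC bias as the whole cause of these calls. Setting proximal replicates 1 and 2 with distal replicate 2 against the other 3 libraries called 920 genes, and 1 gene with the GC trend removed, so GC content bias of the libraries is a candidate cause of that split.

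The 6 libraries of a comparison make 10 splits of 3 against 3, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes and as many lists. edgeR called 2519 genes between proximal and distal cells and at most 920 in another split, 7020 and at most 0 (1176 at an unadjusted p under 0.05) for proximal against monocultured, and 6545 and at most 0 (732 unadjusted) for distal against monocultured. Camera called 11, 18 and 15 lists in these comparisons and at most 9, 13 and 12 in another split. Every other split still sets unequal numbers of libraries of the 2 groups against each other. It thus keeps part of any real difference and puts the rest into the spread. The gene and list counts of these splits are therefore no rate expected by chance.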
